A study of Mus musculus with 2 samples.

How the data were processed

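MicroRNAs are short RNAs, cut from hairpin precursors, that repress messenger RNAs. Small RNA of mouse limb at embryonic day 11.5 was sequenced in 2 libraries of 1 group. The labels number the libraries as biological replicates 1 and 2, and describe them as limb tissue of both sexes pooled from 109 and 88 healthy embryos. Both carry the same donor identifier in the labels, which do not say what it stands for, so p-values and the biological coefficient of variation measure the spread between these samples only. The series holds no second tissue, age or treatment, so no comparison between conditions was possible.

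The deposited unit is the raw count of reads per miRNA gene, with no normalization, in 1 file per library. The notes deposited with each sample name genome assembly mm10 and GENCODE annotation M4. The aligner, the counter and their settings are not given in the sources used here. Each deposited file has no header and lists 3 count columns for 1973 genes, after 4 lines for reads that were unmapped, multimapping, without a feature or ambiguous. The first count column equals the sum of the other 2 for every gene. The second column held nearly all counts and was therefore taken as the sense strand, and the third as the opposite strand; this reading rests on the values. Shares and tests used the sense column.

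Several features of this counting bear on the values. A gene here is a hairpin, so its 5′ and 3′ arms cannot be told apart. Multimapping reads have their own line, so miRNAs encoded by several near-identical hairpins can be counted too low; which genes those reads belong to is not recorded. In all, 923 listed genes share a hairpin stretch of 20 nt with another annotated miRNA gene; 70 of the detected genes are among them, and they hold 8.12% ± 0.07 of the counts (SD, n = 2). At some loci where miRNA genes overlap on opposite strands, the files list only 1 of the genes.

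Symbols, coordinates, host genes and hairpin sequences came from GENCODE M21 on the same assembly, matched by gene identifier without its version. Of the 1973 genes, 1894 matched and 79 did not; the unmatched genes held 4 sense counts in all. Coordinates are 1-based.

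The files hold 6661559 reads for replicate 1 and 7420829 for replicate 2. Sense counts of miRNA genes were 2953085 and 3459176, or 44.3% and 46.6% of reads. Unmapped reads took 23.6% and 23.5%, multimapping reads 24.7% and 23.4%, and reads without a feature 7.44% and 6.47%. The ambiguous line was 0 in both files. These lines stayed out of library sizes and tests. A count of 0 allows a level of up to 1.02 CPM (counts scaled to a common library total) in replicate 1 and 0.867 CPM in replicate 2, from 3 counts of the total. Such floors, and the Wilson 95% intervals, cover counting error only, because PCR copies are not independent molecules.

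CPM was computed over all sense counts, and a gene was called detected at 10 CPM or more in both libraries. Shares and log2 ratios of gene pairs were computed within each library and are given as mean ± SD. That SD covers the spread between the libraries only. With 2 libraries it can fall below the counting error of a pair ratio, which is then given too. A bias of library preparation tied to sequence and shared by both libraries would not show in it. An exact sign-flip test of a pair ratio cannot go below p = 0.5 with 2 libraries, so none was run. Genes with 10 or more counts summed over both libraries were tested for a difference between the libraries with a two-sided exact binomial test against TMM-scaled library sizes, adjusted by Benjamini-Hochberg at 0.05. That test compares these libraries and measures spread beyond counting error; it compares no conditions. edgeR 4.0.16 in R 4.3.3 gave the TMM factors and the common dispersion, and its quasi-likelihood test was not used because the series holds a single group. The log2 ratios are replicate 2 over replicate 1 with a prior count of 0.5. The median log2 ratio of each list was placed among those of 10000 random lists of the same size matched on mean expression. Correlations used log2(CPM + 1). Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 did the rest.

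The 19 gene lists, the 14 gene pairs, the tests and the rule for named genes were fixed before the data were examined. The rule names the 20 most abundant genes, the 3 most abundant detected members of each list, both members of each pair, and the 5 highest and 5 lowest log2 ratios among genes at 100 CPM or more that passed the test. Genes outside it are marked as chosen later, and the genes at loci with opposite-strand counts were also named after those counts were seen. Alternatives covered the detection level, the count column, the denominator, the scaling (total counts, and size factors of DESeq2 1.42.0), the filter, the pseudocount, an overdispersed form of the test, and each library alone. That form used the median squared deviation of all genes, which genes with very large squared deviations hardly move; the mean, which they raise, was tried later.

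The test was tried on simulated counts for the same 422 genes. With counting error only, it called 1.35% of the unchanged genes, and 42% of those changed 1.2-fold, 64% at 1.5-fold, 80% at 2-fold and 90% at 3-fold. With the estimated spread between the libraries added, it called 37.8% of the unchanged genes, and 20.3% with the spread estimated without the 2 genes that differ most, so a call shows a difference between these libraries and not a difference between pools of embryos in general.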

Results

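The data are miRNA counts from embryonic mouse limb at day 11.5, in 2 biological replicates of 1 group. They address which miRNAs this tissue holds and how closely the libraries repeat. The labels give the replicates different numbers of pooled embryos but the same donor identifier, so the spread between them is read here as that of these 2 libraries. Total sense counts were 2953085 in replicate 1 and 3459176 in replicate 2.

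A few hairpins dominated the limb counts. Mir335 was the most abundant miRNA gene, with 11.2% ± 0.14 of all counts (SD, n = 2, as for all shares that follow). It was followed by Mir322 at 7.26% ± 0.11, Mir17 at 7.18% ± 0.11 and Mir196b at 7.03% ± 0.26. Mir214, at 3.91% ± 0.15, and Mir10b, at 3.59% ± 0.02, came next. Together the 10 most abundant genes held 51.5% ± 0.19 of the counts and the top 20 held 68.1% ± 0.39. Of all reads in the files, multimapping and unmapped ones included, the 10 genes held 23.4%. The same 20 genes led in both libraries. Multimapping reads, 24.7% and 23.4% of reads, are in no gene's count, so miRNAs with several near-identical hairpins can rank too low. Wilson 95% intervals for the share of the top 10 were 51.552 to 51.666% in replicate 1 and 51.289 to 51.394% in replicate 2, so the libraries differed by more than counting error.

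These hairpins lie at annotated loci of the mm10 assembly. Mir335 (ENSMUSG00000065501.1) lies on chromosome 6 from 30741299 to 30741396, in an intron of Mest, an imprinted gene expressed from the paternal allele. Mir196b (ENSMUSG00000065443.1) lies on the same chromosome from 52230081 to 52230165, where it overlaps an annotated exon of Hoxa9. Mir322 (ENSMUSG00000065418.1) is on chromosome X from 53054255 to 53054349. Mir17 (ENSMUSG00000065508.1) is on chromosome 14 from 115043671 to 115043754, in an exon of its host transcript Mir17hg. Mir10b, on chromosome 2 from 74726070 to 74726137, lies in introns annotated to Hoxd3 and Hoxd4. Mir214, on chromosome 1 from 162223368 to 162223477, overlaps an exon of the noncoding gene Dnm3os.

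The other genes of the top 20 held between 1.17% and 3.12% of the counts. They were Mir130a, Mir99b, Mir99a, Mir20a, Mir126a, Mir23b, Mir30e, Mir26b, Mir10a, Mir93, Mir140, Mir18, Mir106b and Mirlet7g. In all, 295 genes reached 10 CPM in both libraries, and 13 did so in 1 library only; 195 genes reached 100 CPM in both. Of the 1973 listed genes, 93 reached 1000 CPM in both libraries and 1267 had no sense count in either.

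**Figure D1:**
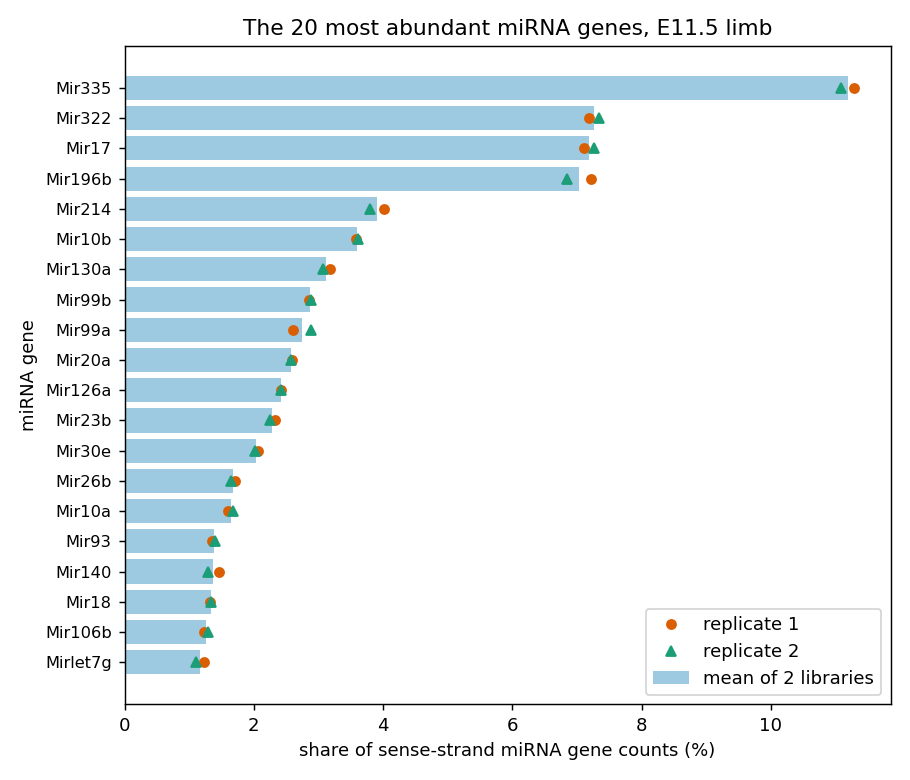
Share of sense-strand miRNA gene counts (%) on the x axis for the 20 most abundant miRNA genes on the y axis. Bars are means of 2 libraries, circles replicate 1 and triangles replicate 2; Mir335 leads at 11.2%, and Mirlet7g closes the group at 1.17%.

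The Mir17-92 cluster and its paralogs, which promote proliferation in many tissues, held the largest share of any list at 14.9% ± 0.16. All 15 members were detected. Mir17 was 5.51 ± 0.06 log2 units above its X-linked paralog Mir106a and 2.51 ± 0.03 above Mir106b, whose hairpin lies in an intron of the replication gene Mcm7. Mir20a held 2.58% and Mir93 1.38% of the counts. Both Mir17 ratios were far larger than the spread between replicates, although the exact sign-flip test cannot pass with 2 libraries. That spread does not measure a bias shared by both libraries, so these are ratios of counts.

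MiRNAs encoded within Hox clusters, the genes that pattern the body axis and the limb, made up 12.9% ± 0.19 of the counts, and all 6 members were detected. Mir196b exceeded Mir196a-1 by 10.64 ± 0.01 log2 units, with 70319 CPM against 44.1 CPM. The counting error of that ratio was larger than its SD, at 0.125 in replicate 1 and 0.118 in replicate 2. Mir196a-1 and Mir196a-2 share hairpin sequence, so reads that fit both can be missing from either count. Mir10b stood 1.13 ± 0.04 log2 units above Mir10a, which held 1.65% of the counts.

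The Mir322-503 cluster, on chromosome X, took 8.21% ± 0.16, with all 5 listed members detected. Mir322 was 4.81 ± 0.07 log2 units above Mir503 in the same cluster, and Mir351 reached 5000 CPM. MiRNAs of cartilage and mesenchyme took 6.19% ± 0.23, with all 8 members detected. Mir140, which is expressed in cartilage, lies in a Wwp2 exon and held 1.38% ± 0.12. It exceeded Mir455 by 3.37 ± 0.13 log2 units. Mir214 was 6.97 ± 0.13 log2 units above its neighbour Mir199a-2, and Mir199b was 5.53 ± 0.22 above Mir199a-1. These Mir199 hairpins share sequence, so reads that fit several can be missing from their counts and their ratios are uncertain. Mir143 was 5.66 ± 0.01 log2 units above Mir145a, the 2 members of a smooth muscle cluster. The counting error of that ratio was larger than its SD, at 0.08 in replicate 1 and 0.07 in replicate 2.

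The imprinted Dlk1-Dio3 cluster on chromosome 12 contributed 4.68% ± 0.27 through many genes of middling level, with 42 of its 47 listed members detected. Mir411, Mir487b and Mir431 led it at 5921, 5414 and 5023 CPM, of which Mir411 and Mir487b share hairpin sequence with another gene. Mir379 was 4.39 ± 0.19 log2 units above Mir410, and Mir127 was 1.65 ± 0.02 above Mir433. The counting error of the Mir127 ratio was 0.03 in each library, larger than its SD. Mir409, Mir376a, Mir380 and Mir299a, of this cluster, were not listed under their own strand, so the share omits them.

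Several further families held smaller shares. The Mir130-301 family took 4.24% ± 0.09, led by Mir130a at 3.12%, and the Mir23-27-24 clusters took 3.46% ± 0.08, led by Mir23b at 2.29%. All 5 listed members of the latter share hairpin sequence with another gene, so their counts are uncertain, and the share is 0 when such genes are left out. The Mir30 family took 2.79% ± 0.02 and the Mir181 family 1.91% ± 0.07, led by Mir30e and Mir181d. In these families 2 of 6 and 4 of 6 members share hairpin sequence with another gene. Their counts can be too low, so the order within each family is uncertain. The let-7 family, which rises as tissues differentiate, held 2.22% ± 0.26, with 9 of its 10 listed members detected. Mirlet7g and Mirlet7i accounted for most of it, at 11686 and 8155 CPM. Reads shared among let-7 copies can be missing, and Mirlet7e was not listed under its own strand. The Mir15-16 family held 0.984% ± 0.040, led by Mir15a at 4686 CPM. Here 2 of the 5 listed members, Mir16-1 among them, share hairpin sequence with another gene, so this order is uncertain too.

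Markers of other cell types differed widely in level. Endothelial markers took 2.43% ± 0.01, nearly all of it Mir126a, which lies in the endothelial gene Egfl7. Epithelial markers took 1.96% ± 0.22 and all 10 were detected, led by Mir205 at 5522 CPM and Mir203 at 3541 CPM. Mir200b was 1.98 ± 0.01 log2 units above Mir141. The counting error of that ratio was larger than its SD, at 0.07 in replicate 1 and 0.06 in replicate 2. White blood cell markers held 0.0724% ± 0.0045, with Mir155 at 413 CPM and Mir223 at 274 CPM. That share omits Mir142, whose reads were counted on the strand opposite a listed gene, and was 0.129% with them. Erythroid markers held 0.0435% ± 0.0078, and the log2 ratio of Mir144 to Mir451a, of the same cluster, was −3.52 ± 0.50. Liver and endocrine markers held 0.105% ± 0.002, led by Mir375 at 890.2 CPM, and Mir122, which is specific to hepatocytes, stood at 18.2 ± 4.9 CPM.

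Myogenic miRNAs held 0.0600% ± 0.0009 of the counts. Mir206, which is specific to skeletal muscle, reached 540.2 ± 16.5 CPM, 4.30 ± 0.31 log2 units above its neighbour Mir133b, which shares sequence with the Mir133a genes. Mir1a-1, Mir133a-1 and Mir133a-2, named after their values were seen, had no sense count in either library. Because near-identical copies of these hairpins exist, a 0 there does not limit the level of the mature miRNA. Neural markers held 0.0394% ± 0.0008, with Mir137 at 210.5 CPM, and 9 of the 10 listed members share hairpin sequence with another gene; without genes that share sequence the list held 0.0229%. The pluripotency clusters held 0.115% ± 0.004, through Mir302a at 376 CPM, Mir302d at 332 CPM and Mir302b at 315 CPM. Without genes that share hairpin sequence, that share was 0.0494%.

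**Figure D2:**
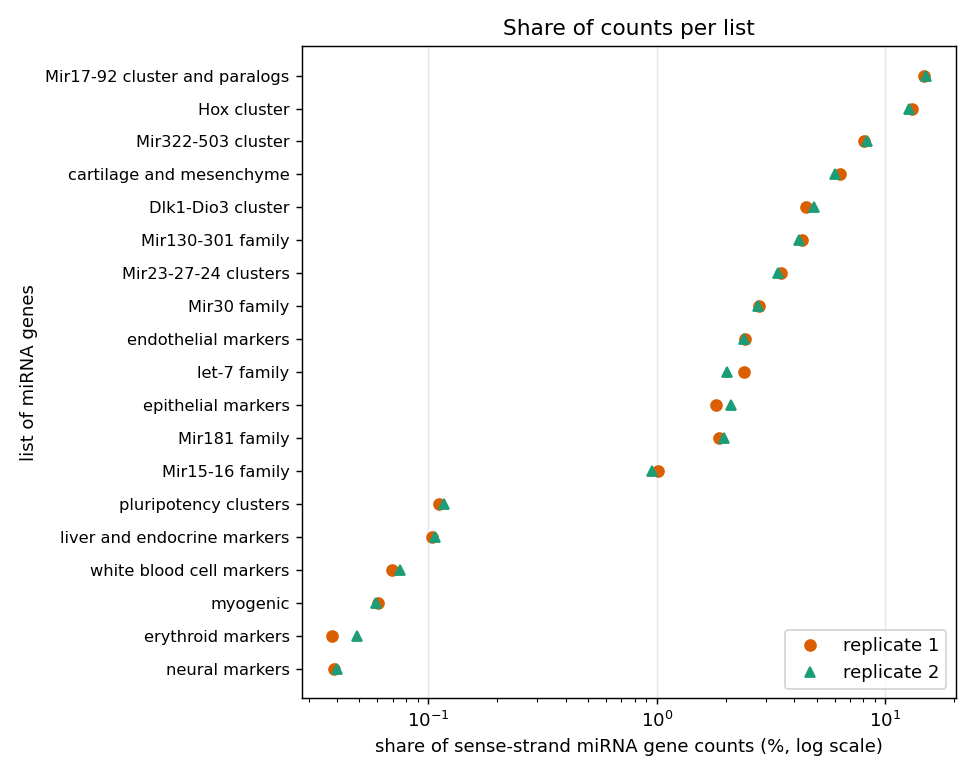
Share of sense-strand miRNA gene counts (%, log scale) on the x axis for each of 19 lists on the y axis, with circles for replicate 1 and triangles for replicate 2. Shares run from 14.9% for the Mir17-92 cluster and paralogs to 0.0394% for neural markers, and the libraries lie close together beside that range.

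The libraries resembled each other closely, with differences beyond counting error. Over 422 tested genes, Pearson's r was 0.994 and Spearman's rho 0.989 across genes, which are not independent replicates. The biological coefficient of variation was 15.1%, and 6.27% without Gm26117 and Mir6538, the 2 genes with the widest differences. Of 201 tested genes with a mean over both libraries of 100 CPM or more, 184 differed by less than 1.2-fold and 3 by more than 1.5-fold, with a median difference of 1.06-fold. By the exact binomial test with Benjamini-Hochberg adjustment, 90 genes differed, 40 higher and 50 lower in replicate 2. Chi-square over degrees of freedom was 18.7, so the files do not repeat 1 library. With total counts as the scaling the same test called 45 higher and 42 lower, and with an overdispersed test 21 higher and 27 lower. That test took the overdispersion from the median gene; taken from the mean over genes, it left 12 calls, 5 higher and 7 lower. Those were Mir182, Mir203, Mir541, Mir351 and Mir99a, higher in replicate 2, and Gm26117, Mir6538, Mirlet7i, Mir140, Mirlet7g, Mir214 and Mir196b, lower. Mir541 was named after its values were seen. The overdispersed test widens the counting error of all genes alike, so genes with many counts can pass at small differences. Mir214 and Mir196b each differed 1.06-fold, close to the median given above.

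The let-7 family was lower in replicate 2 as a block, with a median log2 ratio of −0.32. All 10 tested members had lower values there, and 6 passed, both over all genes and adjusted over the list alone. Mirlet7i had a log2 ratio of −0.36, Mirlet7d of −0.33 and Mirlet7g of −0.17. None of 10000 matched random lists, drawn gene by gene although the 10 members lie at 7 loci, had a median as low. With the overdispersed test 4 of the members passed, or 2 with the mean overdispersion.

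Epithelial markers were higher in replicate 2, with a median log2 ratio of 0.14. All 10 had higher values and 7 passed, also adjusted over the list alone. Mir182 had a log2 ratio of 0.37, Mir203 of 0.30 and Mir205 of 0.20. Of the matched random lists, 16 of 10000 had a median as high, and 5 markers passed the overdispersed test, or 2 with the mean overdispersion. The Dlk1-Dio3 cluster had a median of 0.09, with 39 of 44 tested members above 0, and 8 random lists as high. In it 12 genes passed higher and 0 lower, adjusted over all genes or over the list alone, and the overdispersed test called 5, or 1 with the mean overdispersion. Mir431 had a log2 ratio of 0.15. Random lists drew single genes, whereas the 10 epithelial markers lie at 5 loci and the 44 Dlk1-Dio3 genes at 4, so these ranks can overstate how unusual the medians were.

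The myogenic list had a median of −0.48, at percentile 0.68 of random lists, which rests on members with few counts. Mir206, which holds most of the list's counts, had a log2 ratio of 0.05 and did not pass, and the share of the list was 0.0606% in replicate 1 and 0.0593% in replicate 2. Only 1 of its 6 tested members passed, over all genes or adjusted over the list alone: Mir208b, hosted by the cardiac myosin gene Myh7 and named after its values were seen, with 31.2 CPM in replicate 1 and 8.67 CPM in replicate 2. Among the erythroid markers Mir451a was the 1 of 3 members to pass, also over the list alone, at a log2 ratio of 0.43, while Mir144 had −0.27 and did not pass. The median of that list, −0.27, therefore has the opposite sign to its passing member. Medians of the remaining 15 lists, the erythroid one included, lay between percentiles 6.675 and 91.95. Cartilage and mesenchyme genes went both ways, with 5 of 8 passing over all genes or adjusted over the list alone. Mir140, Mir214, Mir199b and Mir199a-2 passed with lower values in replicate 2 and Mir143 with a higher value. In the Mir17-92 list 3 of 15 genes passed higher and 2 lower, or 7 in all adjusted over the list alone. In the Hox list 1 of 6 passed higher, Mir10a, and 2 lower, Mir196b and Mir196a-2, with 3 over the list alone; Mir196a-2 was named after its values were seen. The overdispersed test kept 4 of the cartilage and mesenchyme calls, 2 of the Mir17-92 calls and 3 of the Hox calls, and 2, 0 and 1 with the mean overdispersion; with the latter neither Mir208b nor Mir451a passed.

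The widest differences at a mean of 100 CPM or more lay outside the lists, at Gm26117 and Mir6538. Gm26117, on chromosome 15 from 74563821 to 74563915 in an exon of Adgrb1, had 263.8 CPM in replicate 1 and 10.99 CPM in replicate 2, a log2 ratio of −4.58. Mir6538, in an intron of Rnf144a, had 225 and 20.8 CPM, a log2 ratio of −3.44. Gm23935, which shares a 20-nt stretch with 5 other miRNA genes, followed at −0.68, then Mirlet7i at −0.36 and Mir6236 at −0.34. Hairpin GC content was 91.6% for Gm26117, 75.5% for Mir6538 and 73.7% for Gm23935. It was 54.1% for Mirlet7i and 56.1% for Mir6236. The highest log2 ratios were those of Mir451a at 0.43 and Mir182 at 0.37, then Mir667, of the Dlk1-Dio3 cluster, at 0.32, Mir203 at 0.30 and Mir325 at 0.30. All 10 passed the binomial test, but Mir6236, Mir667 and Mir325 did not pass the overdispersed one.

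**Figure D3:**
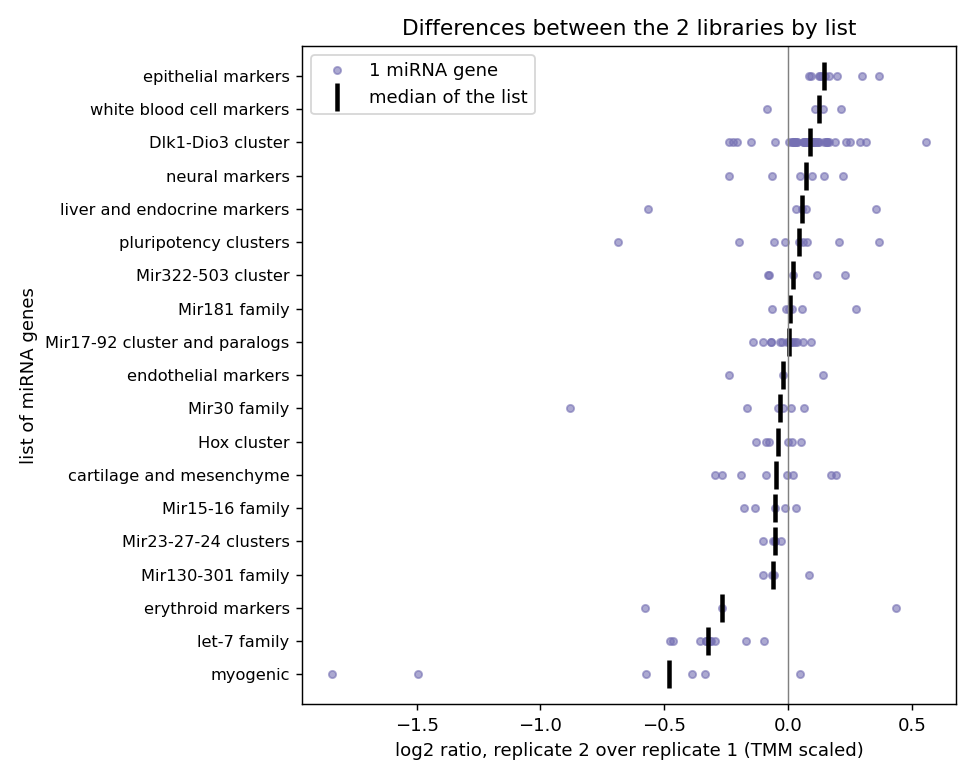
The log2 ratio of replicate 2 over replicate 1, scaled by TMM, on the x axis for each tested gene (points) of 19 lists on the y axis, with the list median as a bar. All let-7 points lie below 0 and all epithelial points above 0.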

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

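Both tests of the opposite-strand counts were chosen after those counts had been seen. The opposite-strand column, which the main shares and tests did not use, held 65685 counts in replicate 1 and 80014 in replicate 2, and 9 genes had 1000 or more in each library, far above the 3 counts that a count of 0 allows.

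Several of these loci belong to the imprinted Dlk1-Dio3 cluster on chromosome 12. Opposite to the listed gene Gm24321, at the site of Mir409, 14590 counts were found in replicate 1 and 20846 in replicate 2. Opposite to Gm25252, at Mir376a, there were 8652 and 10239 counts. Opposite to Mir299b, at Mir299a, there were 4631 and 5566, and opposite to Gm25750, at Mir380, there were 2997 and 3991. Elsewhere, opposite to Gm25927, at Mirlet7e on chromosome 17, there were 15171 and 16987 counts. At Gm25301, opposite to Mir378a, the column held 8593 and 9728, and at Gm24083, opposite to Mir191, it held 6535 and 7554. For Mir497b, opposite to Mir497, the values were 2287 and 2700. For Mir142b, opposite to the white blood cell miRNA gene Mir142, they were 1855 and 1978.

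Stray reads from each listed gene's own strand are argued against, because the own strand held at most 0.245% of the counts at any of these 9 genes over both libraries together, and at most 0.287% in a single library. A candidate explanation is that the counted annotation left out the known miRNA gene on the other strand: 99.9% of all opposite-strand counts lay at listed genes overlapped by such a gene in GENCODE M21, and the 9 genes alone held 99.5%. The design names no biological explanation, and none was tested. Read in this way, the values would place Mirlet7e at 5137 CPM in replicate 1 and 4911 in replicate 2, and Mir409 at 4941 and 6026.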

How the results depend on the processing

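Crediting opposite-strand counts, leaving out genes that share sequence, the mean overdispersion and leaving out Gm26117 and Mir6538 were chosen after the data were examined; all other alternatives were fixed before. No paired analysis was possible because the series holds a single group. With 2 libraries, each library alone lies within 1 SD of the mean by construction, so leaving 1 out says nothing about stability. The 14 pair ratios moved by less than their SD with both strands counted. The let-7, epithelial, Dlk1-Dio3 and myogenic medians kept their sign under total counts and under DESeq2 size factors; a scaling shifts all log2 ratios alike, so it cannot test their percentiles. The count of genes that differ was 87 with total counts, 90 with DESeq2 size factors, 79 without a filter and 96 at 100 or more counts. It fell to 48, all among the 90, with the overdispersed test (overdispersion 2.64), which widens the error of every gene, and to 12 with the overdispersion taken from the mean over genes (18.998). The biological coefficient of variation was between 15.1% and 15.5% under the planned settings and 6.27% without Gm26117 and Mir6538, so these 2 genes set most of it. Detected genes numbered 434 at 1 CPM and 195 at 100 CPM. The correlation was 0.996 with a pseudocount of 10 CPM. The 10 leading genes held 50.3% with both strands counted and 23.4% of all reads. Depth limits what a 0 can show: it allows up to 1.02 CPM in replicate 1 and 0.867 CPM in replicate 2.

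List shares moved by more than their SD where the denominator or the counted genes changed, as each setting's construction brings about. With both strands counted they were 14.6% for the Mir17-92 list, 12.6% for Hox, 0.0587% for myogenic and 8.03% for Mir322-503. In that column Mir23-27-24 held 3.38%, Mir30 2.73%, Mir130-301 4.14%, endothelial markers 2.37% and liver and endocrine markers 0.103%. Crediting opposite-strand counts to the known miRNA raised let-7 to 2.67%, Dlk1-Dio3 to 5.67%, Mir15-16 to 1.04% and white blood cell markers to 0.129%. The larger total lowered Mir17-92 to 14.6%, Hox to 12.6%, myogenic to 0.0587%, Mir322-503 to 8.03% and Mir30 to 2.73%. It also lowered Mir130-301 to 4.14%, endothelial to 2.37%, neural to 0.0386% and liver and endocrine to 0.103%.

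Without Mir335 in the total, 18 lists rose by more than their SD and erythroid markers did not. The values were 16.8% for Mir17-92, 14.5% for Hox, 9.24% for Mir322-503, 6.97% for cartilage and mesenchyme, 5.27% for Dlk1-Dio3 and 4.77% for Mir130-301. Mir23-27-24 held 3.89%, Mir30 3.14%, endothelial 2.73%, let-7 2.504%, epithelial 2.21%, Mir181 2.15% and Mir15-16 1.11%. Pluripotency held 0.129%, liver and endocrine 0.119%, white blood cell 0.0815%, myogenic 0.0675% and neural 0.0444%. Without genes that share a 20-nt stretch, Mir23-27-24 held 0, pluripotency 0.0494%, neural 0.0229%, liver and endocrine 0.0995%, Mir181 1.49%, Mir15-16 0.804% and Dlk1-Dio3 3.82%. With those genes gone from the total, Mir17-92 held 15.5%, Hox 13.8%, Mir322-503 8.93% and cartilage and mesenchyme 6.53%. Mir130-301 held 4.61%, Mir30 3.02%, endothelial 2.64% and myogenic 0.0623%.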

Other observations

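MiRNA genes at the imprinted loci Mest, Dlk1-Dio3, Gnas, Igf2 and H19 held 18.3% ± 0.08 of the counts (SD, n = 2) over 52 genes. The group was chosen after the counts had been seen and does not take in every imprinted locus. Mir335 in Mest supplied 11.2% and the Dlk1-Dio3 cluster 4.68% ± 0.27. At the Gnas locus on chromosome 2, Mir296 and Mir298 together held 1.67% ± 0.05. Mir483, in an intron of the growth factor gene Igf2, held 0.686%, and Mir675, in the neighbouring noncoding gene H19, held 0.0199%.

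Mir99, Mir100 and Mir125 genes, also grouped after the counts had been seen, held 7.31% ± 0.26 over 6 genes. Mir99b and Mir99a led them, and Mir100 added 7985 ± 442 CPM and Mir125a 6384 ± 85 CPM. Mir125b-1 and Mir125b-2 each share hairpin sequence with another gene, so their counts and the share of the group can be too low. Among other abundant genes, likewise named after their values were seen, Mir744, in an intron of Map2k4, reached 10357 ± 368 CPM, and Mir652, in an intron of Tmem164, reached 9819 ± 165 CPM. Mir615, in an intron of Hoxc5, stood at 4250 ± 56 CPM, above its neighbour Mir196a-2 at 1852 ± 107 CPM, which shares sequence with Mir196a-1.

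The paragraphs that follow weigh the let-7 and epithelial lists, 2 of the 4 among 19 whose medians stood out, so the patterns were chosen after the values were seen; the Dlk1-Dio3 list enters only the cluster test and the myogenic list was not weighed. Their tests were also chosen then, except 3: the GC test of the epithelial markers, the GC test of the clusters, and the test of clusters without the epithelial and Dlk1-Dio3 ones. The bound for counting error in the epithelial list was first set at 8 passing markers. After 7 were found it was replaced by 3, from the binomial probability of chance calls. The conclusion on counting error in that list rests on the later bound. Of 201 tested genes with a mean of 100 CPM or more, 83 passed the same test. Passing genes thus argue against counting error but do not set the let-7 or epithelial list apart from other well-counted genes.

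The let-7 family was lower in replicate 2. Counting error is argued against by the 6 of 10 members that passed. A linear trend with hairpin GC content is argued against by a median log2 ratio of −0.34 after that trend was removed. A GC bias of another shape, or one tied to the GC content of the mature read, was not tested. The 5 members that share no hairpin stretch of 20 nt with another miRNA gene all passed, with a median of −0.33. For these 5, loss of reads to exact matches of that length or longer is argued against. Loss of shorter reads, or of reads aligned with mismatches, was not tested, because the aligner and its settings are not given. The other 5, which share such a stretch, had a median of −0.31 and 1 passing. For them loss of reads cannot be told apart from a change in level. The files do not say to which genes the multimapping reads belong. Mirlet7e, read from the opposite strand, had a log2 ratio of −0.08 with a counting error of 0.02; a bias in library preparation tied to the shared let-7 sequence and a difference in age between the pools remain open and were not tested.

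Epithelial markers were higher in replicate 2. Counting error is argued against by 7 of 10 passing markers under the later bound. The linear trend of log2 ratio with hairpin GC content was weak, at −0.035 per 10% GC with a rank correlation of 0.03. A linear trend is argued against as the cause, because the median was at percentile 99.8 of random lists once it was removed. A GC bias of another shape was not tested. A lower share of the main cell type, which would raise markers of the other types alike, stays open: 5 epithelial loci stood 0.19 log2 units above 14 loci of erythroid, white blood cell, endothelial and neural markers (two-sided exact permutation test over loci, p = 0.0175), but 0.04 above the 5 such loci at 100 CPM or more (exact p = 0.675). Without the erythroid Mir451a, at 0.43, the latter gap was 0.11 (exact p = 0.0476). Mir451a had the highest value of the 5, so leaving it out widens the gap by construction, and that p decides nothing. Leaving out Mir223, Mir155, Mir126a or Mir137 instead gave exact p from 0.714 to 0.937. Mir144, of the Mir451a cluster, had −0.27 but lies below 100 CPM. The endothelial Mir126a, the best counted of the 5, had −0.02 with a counting error of 0.007, while Mir223 had 0.14, Mir155 0.11 and Mir137 0.10. The white blood cell gene Mir142, read from the opposite strand, was not among these loci. At 628 CPM in replicate 1 and 572 CPM in replicate 2, it had −0.15 with a counting error of 0.05. Like Mir126a, it was not higher in replicate 2. More limb ectoderm in the second pool cannot be told apart from a lower share of the main cell type. All 10 epithelial markers, led by Mir205 at 5522 CPM and Mir203 at 3541 CPM, had higher values. The series holds no independent count of ectoderm.

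A further hypothesis was that genes of 1 genomic cluster, within 10 kb of each other, shift together between the libraries. Over 139 genes in 40 clusters, 43.9% of the variance in log2 ratio lay between clusters. The median over 10000 shuffles was 28.0% (permutation p = 0.0069). After the linear GC trend was removed the share between clusters was 43.7% (permutation p = 0.0051). Without the clusters of the epithelial and Dlk1-Dio3 lists it was 42.8% over 90 genes in 34 clusters, against a shuffled median of 36.9% (permutation p = 0.2201). Those clusters alone may therefore account for the pattern, though fewer genes were left to test and the p does not show that the other clusters lack it.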
